A study of Mus musculus with 9 samples.

How the data were processed

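RNA was measured by sequencing in HEI-OC1 cells, an immortalised mouse line made from the organ of Corti, the sound-sensing epithelium of the cochlea. The 9 libraries fall into 3 groups of 3: untreated cells (control), cells given hydrogen peroxide (H2O2), and cells given a selenium-carrying nanoreactor, before H2O2 (pretreated H2O2). The nanoreactor is written HCS@Se in the sample descriptions, SCGS in the sample titles and table columns and HSC@Se in the series text, and these were assumed to be 1 agent. Neither a dose nor an exposure time is given, and no group received the nanoreactor without H2O2. Per the labels, RNA was extracted with TRIzol, polyadenylated RNA was selected, strand-specific libraries were made by the dUTP method and they were sequenced on an Illumina instrument as paired reads of 150 bp. The aligner and the counting program are not given in the sources used here, nor whether counting used the strand. The processing notes of the labels name only the human build hg38. The deposited tables nevertheless hold mouse Ensembl gene identifiers with coordinates of the mouse build GRCm38: 30318 of 30411 annotated genes were found in the GENCODE M21 annotation, 99.5% of them with the same start and 97.0% with the same symbol. Positions below are on GRCm38.

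The authors deposited 2 tables, of which the first holds estimated counts per gene for 55401 genes in whole numbers, not scaled to library size. The second holds, for the 30411 genes with a count in any library, the deposited counts again and FPKM (fragments per kilobase of transcript, scaled to library size) computed by the authors. Counts of the 2 tables differed at 0 positions, and the remaining 24990 genes had no count in any library. The counts are called estimated because of their low values: 9836 values were equal to 4, against 4842 equal to 3 and 3136 equal to 5, and 8 and 12 stood out in the same way, with 4196 and 2362 values. Among genes with a mean count of 10 to 20, the variance between replicates was 4.14 times the mean in control, 4.43 times in H2O2 and 4.27 times in pretreated H2O2. On this basis 12 deposited counts were taken as about 3 fragments. Values of 1 and 2 were also frequent, with 7779 and 6750, and 4 counts for every fragment would not give these, so the ratio is approximate and the making of the counts stays unknown. The plan had assumed raw read counts. An alternative with all counts divided by 4 was added for this reason.

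Library totals were 60716028, 55395418 and 64993443 deposited counts in control replicates 1 to 3, 59996980, 65228446 and 65666622 in H2O2, and 67215208, 63329281 and 64312474 in pretreated H2O2. A gene at 12 counts in a library lies between 0.182 and 0.214 CPM (counts scaled to a common library size by the cpm function of edgeR), which is the floor used for groups without a count. A fold against a group with no count is given as a lower bound against that floor, and genes with no more than 12 counts over a group are given as levels without a fold. Floors cover counting error only, since reads without molecular identifiers are not independent molecules. Intervals given below, for list medians, percentages of genes and an odds ratio, take genes as the units. They treat genes as independent and include neither counting error nor the spread between libraries.

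Differential expression was tested with edgeR 4.0.16 in R 4.3.3: TMM library scaling, the default filter on low counts by group (18092 genes kept), and a quasi-likelihood test on all 9 libraries with 1 mean per group. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, with no minimum fold change. CPM values use the TMM-scaled library sizes, a detail that the plan left open, and are given as mean ± SD over 3 libraries; log2 fold changes come from the edgeR fit with its standard error. Lists of genes were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Of 43 lists, 42 had at least 5 tested members. Camera asks whether a list's genes moved relative to all other genes. Each list was also tested with the correlation estimated from the data, and with fry, which asks whether a list's genes move on balance one way without comparing them with other genes. For H2O2 calls, the number called in the opposite direction in pretreated H2O2 was counted, and the covariance of the 2 changes was set against 20 simulated data sets with no effect of pretreatment. Group values without a model were compared by two-sided exact permutation tests in scipy 1.17.1 under Python 3.11.15. With 3 libraries against 3 the smallest p such a test can give is 0.1.

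The groups, the tests, the lists, the alternatives and the rule for naming genes were chosen before the data were examined. The rule names, per comparison, the 8 largest rises and the 8 largest falls among called genes with a mean of at least 1 CPM over the 9 libraries and no overlap between the groups, leaving out unnamed gene models and pseudogenes; up to 4 members of each described list, those with the smallest p; and 19 genes of oxidative stress, selenium, iron and cell death whatever their values, which are Hmox1, Nqo1, Gclm, Slc7a11, Txnrd1, Srxn1, Gpx4, Gpx1, Acsl4, Tfrc, Fth1, Slc40a1, Cat, Sod1, Sod2, Cdkn1a, Ddit3, Chac1 and Ptgs2. Any gene outside the rule is marked as chosen after its values were seen.

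Alternatives concerned the scaling (DESeq2 size factors, or total counts alone), the filter (none, or at least 1 CPM in 3 libraries), the test (DESeq2 1.42.0, or limma on the authors' FPKM with pseudocounts of 1 and 0.1 and with or without a minimum mean of 0.5), the 2 compared groups alone, a minimum log2 fold change of 1, the replicate number as a block, and each library left out in turn in 9 fits. DESeq2 came with its own scaling and its own filter, and limma on FPKM changed the unit, the scaling, the test and the filter together (12873 genes tested with the minimum mean, 30411 without). Added after the data were seen were the counts divided by 4, offsets per library for transcript length and GC content, the same offsets with the replicate block, the mitochondrial chromosome left out, and genes under 1 CPM on average in control and in H2O2 left out. Transcript length and GC content were found for 18060 of 18092 tested genes (99.82%).

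The pipeline was tested on simulated data built from these libraries. Of 50 genes changed at each size, it recovered 52%, 78%, 90% and 96% at folds of 1.2, 1.5, 2 and 4 for H2O2 against control, 56%, 68%, 96% and 100% for pretreated H2O2 against H2O2, and 54%, 78%, 80% and 94% for pretreated H2O2 against control. Unchanged genes made up 3.66%, 2.44% and 4.97% of the calls. These simulations drew every gene with 1 fixed dispersion and changed only 200 genes, none of them among those of lowest counts. The percentages describe that setting and need not hold for the real libraries, where 8817 to 11511 genes were called. Equal replicate numbers were checked as a sign of a shared culture day. Residuals of control and pretreated H2O2 libraries with equal numbers correlated at r = 0.332, 0.137 and 0.249 across genes, and those with unequal numbers at −0.277 to 0.061. Control and H2O2 libraries with unequal numbers reached 0.256, so replicate numbers may pair control with pretreated H2O2, but this is not settled. Blocked values stand beside the comparison of pretreated H2O2 with control. Genes are not independent replicates. No library duplicated another: between replicates the chi-square per degree of freedom ran from 7.67 to 10.53, and from 2.08 to 2.94 with counts divided by 4. Nothing was left out: 0 sample columns of the tables went unused. P-values of single genes, of fry and of the permutation tests measure only the spread between these 9 libraries. Camera sets the genes of a list against all other genes. Its p-values therefore also rest on the spread between genes and on the correlation taken between them. The labels call the libraries replicate biosamples, and nothing says that they are separate cultures, so the spread between libraries may be technical.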

Results

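Messenger RNA was sequenced in HEI-OC1 cells, an immortalised mouse line from the cochlear organ of Corti, in 3 groups with 3 libraries each: control, H2O2 and pretreated H2O2. H2O2 is an oxidant used to stress cells, and the pretreatment was a selenium-carrying nanoreactor. Libraries held between 55395418 and 67215208 deposited counts. Every gene tested below was compared by edgeR over 18092 genes, levels are CPM ± SD with n = 3 per group, and named genes said to rise or fall had no overlap between the libraries of the groups compared unless stated. Libraries of a group resembled each other more than those of other groups. Spearman correlations across genes were 0.993 within groups, 0.980 to 0.982 between control and H2O2, 0.950 to 0.951 between control and pretreated H2O2, and 0.953 to 0.955 between H2O2 and pretreated H2O2.

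The comparison of H2O2 with control asks what the oxidant changed in these cells. The p53 target Cdkn1a, an inhibitor of cell cycle kinases (ENSMUSG00000023067, chromosome 17, 29090976 to 29100727 on GRCm38), rose 3.77-fold, from 24.1 ± 1.63 to 90.7 ± 4.87 CPM (log2 fold change 1.91, SE 0.047, adjusted p = 1.22e-11). Hspa1b, an inducible chaperone of the heat shock response (ENSMUSG00000090877, chromosome 17, 34956436 to 34959238), rose 6.86-fold, from 12.8 ± 0.686 to 88.1 ± 2.05 CPM (SE of the log2 fold change 0.054, adjusted p = 2.31e-12). Messenger RNA for cytosolic ribosomal proteins rose as a group in 77 of 77 tested genes, while RNA encoded by the mitochondrial genome fell in 14 of 15. Neither list was called when the correlation between genes was estimated (adjusted p = 0.0629 with an estimated correlation for the first and adjusted p = 0.0942 with an estimated correlation for the second). The mitochondrial share of all counts was 2.66 ± 0.069% in control and 1.01 ± 0.003% in H2O2 (two-sided exact permutation p = 0.1, the smallest that 3 libraries against 3 allow).

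Of 18092 genes tested, 8817 (48.7%) were called, 4452 higher and 4365 lower in H2O2. A change of at least 2-fold was found in 484 of those higher and 621 of those lower. In 277 of the 484, control held no count or no more than 12 counts over its 3 libraries. The 2 groups did not overlap in 55.9% of all tested genes, where chance gives 10%.

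**Figure D1:**
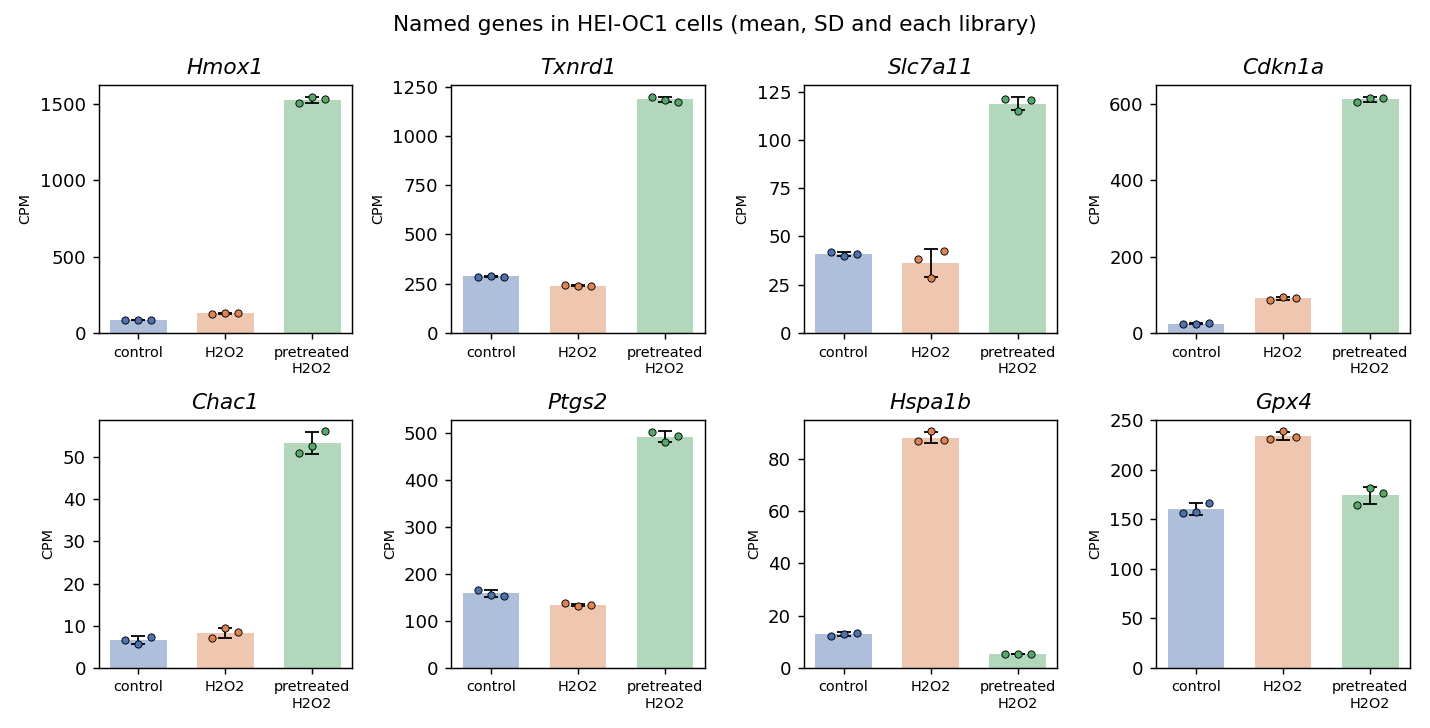
Level in CPM (y axis, from 0) of 8 genes in control, H2O2 and pretreated H2O2, with bars for the group mean, error bars for the SD and points for the 3 libraries of each group. Hmox1 stood at 85.0, 128 and 1527 CPM and Gpx4 at 160, 234 and 174 CPM in the 3 groups.

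Among antioxidant enzymes, which remove peroxides and superoxide, 22 of 29 tested genes rose and 2 fell (23 and 2 when adjusted over the list alone). Thioredoxin Txn1 rose from 354 ± 5.95 to 537 ± 1.86 CPM, the superoxide dismutase Sod1 from 121 ± 3.71 to 186 ± 5.9 CPM and the peroxiredoxin Prdx6 from 162 ± 0.39 to 227 ± 0.322 CPM. The list passed with a median log2 fold change of 0.41 and adjusted p = 2.19e-06; it had adjusted p = 0.0629 with an estimated correlation. Sod2, the mitochondrial superoxide dismutase, rose from 56.9 ± 1.55 to 68.3 ± 1.98 CPM (adjusted p = 0.000102), and catalase, Cat, from 48.1 ± 2.01 to 57.5 ± 1.99 CPM (adjusted p = 0.000184), a call that ended with offsets for transcript length and GC content (log2 fold change 0.10). Targets of the oxidant-responsive factor NRF2 rose in 19 of 32 and fell in 7 (21 and 7 when adjusted over the list alone; adjusted p = 0.00387). The same list had adjusted p = 0.0843 with an estimated correlation. Its heme-degrading enzyme Hmox1 (ENSMUSG00000005413, chromosome 8, 75093621 to 75100589) rose 1.51-fold from 85.0 ± 1.83 to 128 ± 4.53 CPM (SE 0.028, adjusted p = 2.48e-09). The quinone reductase Nqo1 rose 1.40-fold, and the iron-storing ferritin heavy chain Fth1 rose 1.42-fold, from 628 ± 8.08 to 890 ± 9.15 CPM. Thioredoxin reductase Txnrd1, a selenoprotein, fell from 288 ± 2.82 to 240 ± 3.12 CPM (log2 fold change −0.26, adjusted p = 1.91e-07). Gclm, a subunit of the enzyme that starts glutathione synthesis, fell by 0.15 on the log2 scale (adjusted p = 0.00168) but was higher with the offsets, at 0.15. Sulfiredoxin, Srxn1, at 83.4 ± 1.34 and 85.3 ± 3.71 CPM, did not pass (log2 fold change 0.03, adjusted p = 0.475; −0.07 with the offsets and −0.01 without H2O2 replicate 1).

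Selenoproteins and selenium-handling genes rose in 11 of 27 and fell in 6, unchanged when adjusted over the list alone, and the list did not pass (adjusted p = 0.287). Gpx4, the glutathione peroxidase that reduces lipid peroxides (ENSMUSG00000075706, chromosome 10, 80047166 to 80056439), rose 1.46-fold from 160 ± 6.05 to 234 ± 3.97 CPM (SE 0.037, adjusted p = 6.82e-08). Gpx1 rose 1.49-fold from 179 ± 8.38 to 267 ± 3.46 CPM. Glutathione synthesis and transfer genes rose in 12 of 28 and fell in 3, the same numbers when adjusted over the list alone (adjusted p = 0.0297). That list had adjusted p = 0.0927 with an estimated correlation and 0.51 with the offsets. Slc3a2, a chain of the cystine importer, rose 1.31-fold, whereas its partner Slc7a11, at 40.9 ± 1.01 and 36.3 ± 7.29 CPM, did not pass (log2 fold change −0.17, adjusted p = 0.21; 0.44 and called with the offsets). Of the iron and lipid genes named in advance, the lipid-activating enzyme Acsl4 fell 1.34-fold from 111 ± 8.29 to 82.8 ± 1.76 CPM, and the iron exporter Slc40a1 was at the floor in all 3 groups. The transferrin receptor Tfrc, at 220 ± 4.66 and 217 ± 5.88 CPM, did not pass (adjusted p = 0.673) but was called higher with the offsets (log2 fold change 0.20). Ferroptosis expression markers, genes whose RNA often accompanies this iron-dependent death, rose in 8 of 12 and fell in 1, also when adjusted over the list alone (adjusted p = 0.0268; adjusted p = 0.0927 with an estimated correlation). They include Atf3, up from 0.43 ± 0.0924 to 4.66 ± 0.572 CPM, and Ptgs2, a prostaglandin synthase that fell from 158 ± 6.86 to 134 ± 2.78 CPM. Chac1, which degrades glutathione, stood at 6.54 ± 0.888 and 8.31 ± 1.15 CPM with overlapping libraries (adjusted p = 0.0256). Its call was lost in several alternatives, among them those without control replicate 2 (log2 fold change 0.24), without H2O2 replicate 2 (0.25), without H2O2 replicate 3 (0.33) and with the offsets (0.12).

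Targets of p53 rose in 14 of 29 and fell in 3, also when adjusted over the list alone (adjusted p = 0.00553; adjusted p = 0.0655 with an estimated correlation). The kinase gene Plk2 rose 1.41-fold, the growth-restraining Btg2 rose 2.41-fold from 12.6 ± 1.27 to 30.4 ± 1.53 CPM, and Bax, which permeabilises mitochondria in apoptosis, rose 1.64-fold. Integrated stress response genes, controlled by ATF4 and CHOP, rose in 21 of 34 and fell in 6 (22 and 6 when adjusted over the list alone; adjusted p = 0.0015). Their list had adjusted p = 0.0629 with an estimated correlation. Atf4 rose from 290 ± 2.88 to 425 ± 10.2 CPM and Ddit3, which encodes CHOP, from 7.61 ± 0.227 to 13.1 ± 0.81 CPM. Transfer RNA synthetase genes rose in 14 of 20 and fell in 3 (15 and 3 when adjusted over the list alone; adjusted p = 0.00359; adjusted p = 0.0927 with an estimated correlation), with Sars up from 267 ± 2.96 to 349 ± 6.63 CPM. Heat shock genes rose in 17 of 21 and fell in 3 (18 and 3 when adjusted over the list alone; adjusted p = 2.33e-05; adjusted p = 0.0629 with an estimated correlation). Beside Hspa1b, its near-identical neighbour Hspa1a rose from 3.12 ± 0.258 to 21.4 ± 0.881 CPM, and the division of reads between these 2 genes is uncertain. The constitutive chaperone Hspa8 rose 1.49-fold from 2493 ± 53.2 to 3705 ± 54.4 CPM.

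Ribosomal protein genes had a median log2 fold change of 0.66, and all 77 also rose when adjusted over the list alone (adjusted p = 1.46e-31; adjusted p = 0.0629 with an estimated correlation). Rps2 rose from 2461 ± 9.83 to 3769 ± 46.7 CPM and Rpl23 from 305 ± 3.75 to 512 ± 1.59 CPM. Respiratory chain subunits encoded in the nucleus rose in 68 of 69, as they did when adjusted over the list alone, with a median of 0.50 (adjusted p = 3.24e-20; adjusted p = 0.0629 with an estimated correlation). Atp5b, a subunit of ATP synthase, rose 1.37-fold and Cox5a, of cytochrome oxidase, 1.54-fold. With the offsets these medians were 0.30 and 0.17. Mitochondrially encoded genes fell in 14 of 15 with a median of −1.50, also when adjusted over the list alone (adjusted p = 6.34e-11; adjusted p = 0.0942 with an estimated correlation). Cytochrome oxidase subunit mt-Co1 fell 3.36-fold from 9136 ± 224 to 2719 ± 7.3 CPM. The complex I subunit mt-Nd6 (ENSMUSG00000064368, mitochondrial chromosome, 13552 to 14070) fell 23.1-fold from 294 ± 11.9 to 12.7 ± 1.74 CPM (SE 0.084, adjusted p = 1.76e-12). In the other direction went the small ribosomal RNA mt-Rnr1, which rose from 91.2 ± 3.88 to 114 ± 4.86 CPM; it was chosen after its values were seen, and alternatives were not run for it here.

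Energy metabolism genes rose in 4 lists. Tricarboxylic acid cycle genes rose in 19 of 23 and fell in 2, also when adjusted over the list alone (adjusted p = 1.77e-05; adjusted p = 0.0747 with an estimated correlation), among them malate dehydrogenase Mdh2, up 1.36-fold. Fatty acid oxidation genes rose in 18 of 27 and fell in 1 (19 and 1 when adjusted over the list alone; adjusted p = 0.000605; adjusted p = 0.0629 with an estimated correlation). The member that fell was Cpt1a, the gate of fatty acid entry into mitochondria, down 1.36-fold from 79.5 ± 1.98 to 58.3 ± 1.05 CPM. Pentose phosphate and NADPH genes rose in 12 of 17 with none lower, also when adjusted over the list alone (adjusted p = 0.000966; adjusted p = 0.0927 with an estimated correlation), and Pgd rose 1.21-fold. Glycolysis genes rose in 14 of 23 and fell in 4, also when adjusted over the list alone (adjusted p = 0.0105, and adjusted p = 0.078 with an estimated correlation), with Tpi1 up 1.33-fold. The 22 symbols of this list gave 23 tested gene identifiers, so a symbol can stand for more than 1 identifier. Fatty acid synthesis genes fell in 14 of 26 and rose in 6, also when adjusted over the list alone (adjusted p = 0.0211; adjusted p = 0.0991 with an estimated correlation, and 0.117 with the offsets); their median was −0.23 and their mean 0.13. The desaturase Scd2 fell from 2570 ± 11.5 to 1804 ± 13 CPM, and Fasn fell 1.51-fold but was called higher with the offsets (0.16).

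Fibroblast and mesenchyme markers fell in 10 of 13 and rose in 1, also when adjusted over the list alone (adjusted p = 6.48e-05; adjusted p = 0.078 with an estimated correlation). The growth factor receptor Pdgfrb fell 1.84-fold from 348 ± 6.94 to 189 ± 3.22 CPM and collagen Col1a1 1.46-fold from 1598 ± 7.6 to 1094 ± 7.51 CPM. Extracellular matrix and TGF-beta target genes fell in 20 of 29 and rose in 3, also when adjusted over the list alone (adjusted p = 0.000415; adjusted p = 0.0629 with an estimated correlation). Fibronectin, Fn1, fell 1.66-fold, while the smooth muscle actin Acta2 rose from 1240 ± 8.46 to 1789 ± 8.03 CPM. With the offsets the log2 fold change of Fn1 was −0.17 in place of −0.73, that of Acta2 0.28 in place of 0.53 and that of Col1a1 −0.10 in place of −0.55. Genes of the G1 and S phases rose in 21 of 32 and fell in 5 (22 and 5 when adjusted over the list alone; adjusted p = 0.00593; adjusted p = 0.121 with an estimated correlation), with Cdk4 up 1.33-fold and Pcna up 1.35-fold. Lysosome genes rose in 18 of 34 and fell in 8 (18 and 9 when adjusted over the list alone; adjusted p = 0.0325; adjusted p = 0.0927 with an estimated correlation), with the cathepsin Ctsl up 1.28-fold. The lysosome call also ended with the replicate block, at 0.0505, without genes under 1 CPM in control and H2O2, and with the offsets. The 8 largest rises were all of genes without a count in control that reached at most 0.676 CPM in H2O2, led by AI854703, Il17f and Neurog2 (0.676 ± 0.129, 0.547 ± 0.13 and 0.434 ± 0.128 CPM, at least 3.15-fold, 2.55-fold and 2.02-fold higher). These 8 genes met the minimum mean of 1 CPM over the 9 libraries only through their level in pretreated H2O2. Of the 8 largest falls, 7 were mitochondrial genes.

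Camera called 20 of 42 lists, 16 higher and 4 lower. None of the 20 was called with an estimated correlation. Other divisions of the 6 libraries into 3 and 3 called up to 6 lists. Such divisions mix libraries of both groups on each side, here and below, so their numbers are no rate of false calls. Over all camera alternatives the lowest adjusted p of these lists ran from 4.9e-32 to 0.0301, and the value with an estimated correlation was the highest except for glutathione and fatty acid synthesis, as given. With the offsets 6811 genes were called, 5285 of them shared with the 8817 and 377 in the opposite direction, and many changes were smaller: the log2 fold change of Hmox1 was 0.30 in place of 0.60 and that of Gpx4 0.27 in place of 0.55. Of the other genes named for this comparison, the change kept its direction and was over 1.5 times smaller with the offsets for Rps2, Rpl23, Atp5b, Cox5a, Mdh2, Tpi1, Txn1, Prdx6, Gpx1, Nqo1, Fth1, Atf4, Ddit3, Ptgs2, Acsl4, Scd2, Pdgfrb, Cdk4 and Pcna. It was larger for Sod2 (0.59 in place of 0.26) and Ctsl (0.72 in place of 0.36).

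Pretreated H2O2 was compared with H2O2 to ask what the nanoreactor given beforehand changed in oxidant-treated cells. Hmox1 rose a further 11.9-fold, from 128 ± 4.53 to 1527 ± 20.2 CPM (log2 fold change 3.57, SE 0.029, adjusted p = 3.98e-16). Mdm2, the p53 target whose product degrades p53 (ENSMUSG00000020184, chromosome 10, 117688875 to 117710758), rose from 67.7 ± 0.894 to 881 ± 21.3 CPM (log2 fold change 3.70, SE 0.026, adjusted p = 1.88e-16). Thioredoxin reductase Txnrd1 (ENSMUSG00000020250, chromosome 10, 82833951 to 82897712) rose 4.93-fold from 240 ± 3.12 to 1186 ± 13.7 CPM (SE 0.02, adjusted p = 5.3e-16). In the other direction Hspa1b fell 16.7-fold from 88.1 ± 2.05 to 5.28 ± 0.123 CPM, and Hmgcs1, an early enzyme of cholesterol synthesis, fell 3.66-fold from 308 ± 5.6 to 84.2 ± 3 CPM. The number of genes with a count was 20690 ± 212 in H2O2 and 24106 ± 54.7 in pretreated H2O2 (two-sided exact permutation p = 0.1, the smallest possible).

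Here 11511 genes (63.6%) were called, 5856 higher and 5655 lower in the pretreated group, 2805 and 843 of them by at least 2-fold. In 982 of the 2805, H2O2 held no count or no more than 12 counts over the group. Non-overlapping groups made up 69.7% of tested genes, where chance gives 10%. The balance of higher and lower genes differed between alternatives. Total counts alone gave 5604 higher and 6005 lower, and a filter at 1 CPM gave 4998 and 4973 among 13500 genes. On the same comparison limma on the authors' FPKM gave 3676 higher and 5701 lower among 12873 genes with the minimum level, but 6513 higher and 5724 lower among 30411 without it, and the offsets gave 6646 higher and 4526 lower.

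Integrated stress response genes rose in 32 of 34 with none lower, also when adjusted over the list alone (median log2 fold change 0.93, adjusted p = 1.25e-12). The stress-induced Sesn2 rose 18.5-fold from 21.6 ± 0.929 to 400 ± 4.91 CPM, the pseudokinase gene Trib3 8.27-fold from 6.73 ± 0.371 to 55.6 ± 1.31 CPM, and the amino acid transporter chains Slc3a2 and Slc7a5 rose 2.24-fold and 2.45-fold. Ddit3 rose 1.89-fold to 24.8 ± 0.382 CPM. Targets of p53 rose in 23 of 29 and fell in 4, also when adjusted over the list alone (median 0.99, adjusted p = 1.51e-06), and Cdkn1a rose 6.74-fold to 612 ± 6.44 CPM. Ferroptosis expression markers rose in 11 of 12 and fell in 1, also when adjusted over the list alone (median 1.70, adjusted p = 6.12e-06). Among them, Ptgs2 rose 3.67-fold from 134 ± 2.78 to 492 ± 10.8 CPM and Chac1 6.40-fold from 8.31 ± 1.15 to 53.3 ± 2.62 CPM. Sesn2, Atf4, Ddit3, Chac1, Trib3, Atf3, Ddit4 and Slc7a11 are members of both the stress response and the ferroptosis marker lists. Sesn2 is also in the p53 list, and Hmox1 is in both the NRF2 and the ferroptosis marker lists. These lists are therefore not independent. Immediate early genes, first responders to growth and stress signals, rose in 24 of 34 and fell in 8, also when adjusted over the list alone (adjusted p = 0.000196; adjusted p = 0.099 with an estimated correlation). Ccn2 rose 5.14-fold from 184 ± 2.14 to 948 ± 14.8 CPM and Fosl1 6.70-fold. Transfer RNA synthetase genes rose in 12 of 20 and fell in 5, also when adjusted over the list alone (adjusted p = 0.0207; adjusted p = 0.167 with an estimated correlation), with Gars up 1.85-fold and Nars up 2.24-fold.

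Targets of NRF2 rose in 19 of 32 and fell in 10, also when adjusted over the list alone (median 0.31, adjusted p = 0.0215; adjusted p = 0.138 with an estimated correlation). The autophagy adaptor Sqstm1 rose 3.09-fold from 357 ± 2.48 to 1103 ± 13.8 CPM, and Srxn1, Nqo1 and Gclm rose 2.35-fold, 1.46-fold and 1.59-fold. Antioxidant enzymes went the other way, with 20 of 29 lower and 3 higher (21 and 3 when adjusted over the list alone; median −0.27, adjusted p = 0.00295). That list had adjusted p = 0.0711 with an estimated correlation and 0.202 with the offsets, and it was not called without genes under 1 CPM in control and H2O2. Prdx2 fell 1.39-fold from 348 ± 1.47 to 250 ± 3.26 CPM, Sod1 1.34-fold from 186 ± 5.9 to 139 ± 2.77 CPM and the endoplasmic reticulum peroxidase Gpx8 1.57-fold. Sod2 fell 1.11-fold (adjusted p = 0.00437), a call that ended with DESeq2 and without genes under 1 CPM in control and H2O2, and Cat, at 57.5 ± 1.99 and 56.1 ± 0.696 CPM, did not pass (log2 fold change −0.04, adjusted p = 0.456; 0.13 and called with the offsets, 0.01 with DESeq2).

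Selenoprotein and selenium-handling genes rose in 8 of 27 and fell in 13 (8 and 14 when adjusted over the list alone) and did not pass as a list (adjusted p = 0.284). Beside Txnrd1, which rose, the selenium-activating Sephs2 fell 1.56-fold from 59.8 ± 1.87 to 38.5 ± 1.08 CPM and Eefsec, the factor that delivers selenocysteine to ribosomes, fell 1.56-fold from 70.2 ± 1.95 to 45.1 ± 1.31 CPM. Gpx4 fell 1.34-fold from 234 ± 3.97 to 174 ± 8.56 CPM (log2 fold change −0.43, SE 0.037, adjusted p = 5.21e-07; −0.16 with the offsets). Gpx1 fell 1.21-fold, from 267 ± 3.46 to 221 ± 2.88 CPM, but its log2 fold change was 0.01 with the offsets. Glutathione genes rose in 9 of 28 and fell in 10, also when adjusted over the list alone (adjusted p = 0.797), and Slc7a11 rose 3.27-fold from 36.3 ± 7.29 to 119 ± 3.49 CPM. Iron handling genes rose in 11 of 29 and fell in 12 (adjusted p = 0.924), with Tfrc up 1.57-fold to 341 ± 12.7 CPM and Steap1 down 2.37-fold. Acsl4 and Fth1 did not pass (82.8 ± 1.76 and 87.3 ± 0.59 CPM, adjusted p = 0.154; 890 ± 9.15 and 911 ± 4.9 CPM, adjusted p = 0.12), and Fth1 was called higher with the offsets (0.26).

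Cholesterol synthesis and uptake genes fell in 23 of 25 and rose in 1, also when adjusted over the list alone (median −1.02, adjusted p = 1.44e-10). Fdft1, which makes squalene, fell 2.95-fold, Msmo1 2.71-fold and Acat2 2.45-fold. Fatty acid synthesis genes fell in 18 of 26 and rose in 2, also when adjusted over the list alone (median −0.43, mean 0.07, adjusted p = 6.75e-05), with Scd2 down 2.30-fold to 783 ± 21.4 CPM and the elongase Elovl6 down 2.50-fold. Fatty acid oxidation genes fell in 22 of 27 and rose in 3, also when adjusted over the list alone (median −0.45, adjusted p = 1.15e-05), and the acyl-CoA dehydrogenase Acadm fell 2.05-fold from 106 ± 3.78 to 51.5 ± 3.09 CPM. Interferon response genes fell in 26 of 33 and rose in 2 (27 and 2 when adjusted over the list alone; median −0.92, adjusted p = 5.2e-07). The interferon regulator Irf1 fell 4.41-fold from 124 ± 2.46 to 28.1 ± 1.02 CPM and the signal transducer Stat2 3.99-fold. Genes of the G2 and M phases fell in 34 of 36 with none higher, also when adjusted over the list alone (adjusted p = 6.79e-12; adjusted p = 0.0647 with an estimated correlation). The proliferation marker Mki67 fell 2.01-fold from 287 ± 5.95 to 143 ± 0.16 CPM and the mitotic kinase Plk1 1.92-fold.

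**Figure D2:**
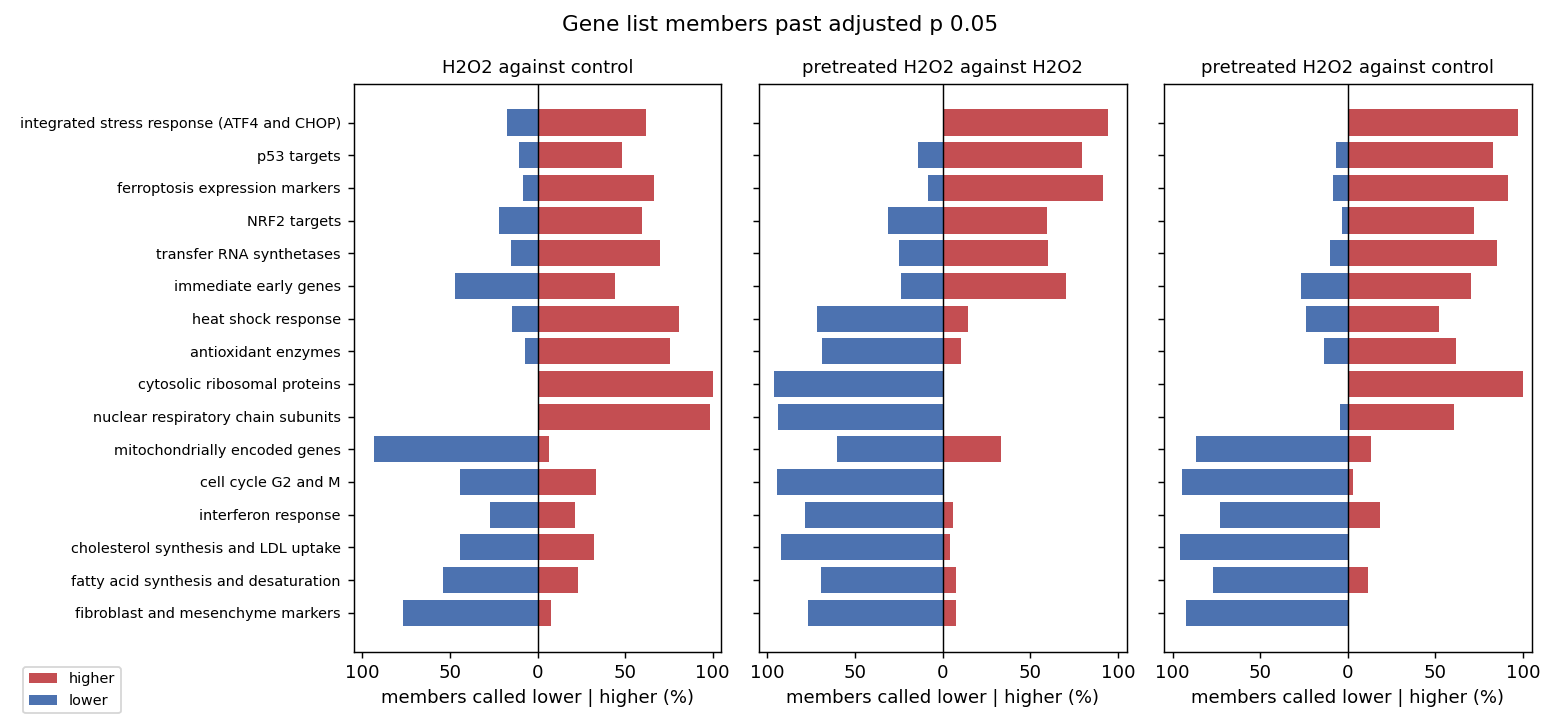
Percent of the tested members called higher (right of 0) or lower (left of 0) for 16 gene lists, in 1 panel per comparison. Ribosomal protein genes rose in 77 of 77 in H2O2 against control and fell in 74 of 77 in pretreated H2O2 against H2O2, and integrated stress response genes rose in 32 of 34 in the latter.

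Ribosomal protein genes fell in 74 of 77 with a median of −0.30, also when adjusted over the list alone (adjusted p = 9.67e-14; adjusted p = 0.137 with an estimated correlation); Rpl3 fell from 966 ± 14.2 to 716 ± 2.74 CPM (log2 fold change −0.43, and −0.19 with the offsets). Nuclear respiratory chain subunits fell in 65 of 69, also when adjusted over the list alone (adjusted p = 7.96e-12; adjusted p = 0.099 with an estimated correlation), with Ndufv2 down 1.42-fold. Tricarboxylic acid cycle genes fell in 19 of 23 and rose in 1 (20 and 1 when adjusted over the list alone; adjusted p = 2.48e-05; adjusted p = 0.081 with an estimated correlation), with Idh2 down 1.53-fold. Pentose phosphate and NADPH genes fell in 14 of 17 and rose in 2, also when adjusted over the list alone (adjusted p = 0.00632; adjusted p = 0.145 with an estimated correlation), and Idh1 fell 2.35-fold. This call and the next were also lost without genes under 1 CPM in control and H2O2 and with the offsets. Heat shock genes fell in 15 of 21 and rose in 3, also when adjusted over the list alone (adjusted p = 0.00699; adjusted p = 0.099 with an estimated correlation). Hspa8 fell 1.99-fold from 3705 ± 54.4 to 1865 ± 44.1 CPM, while the chaperone Hsp90aa1 rose 1.44-fold. Fibroblast markers fell in 10 of 13 and rose in 1, also when adjusted over the list alone (adjusted p = 0.000196; adjusted p = 0.099 with an estimated correlation), with Pdgfrb down 3.10-fold to 61.1 ± 1.88 CPM and the transcription factor Pou3f4 down 2.30-fold. Mitochondrially encoded genes rose in 5 of 15 and fell in 9 and did not pass (adjusted p = 0.392): mt-Rnr2, the large ribosomal RNA, rose 5.05-fold from 134 ± 1.84 to 674 ± 14.3 CPM, and mt-Atp6 fell 1.65-fold.

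The largest rises were of genes with no count in H2O2: the glutamate receptor Grm4 at 5.27 ± 0.512 CPM, Cym at 4.96 ± 0.7 CPM, Asgr1 at 4.74 ± 0.523 CPM were at least 26.5-fold, 24.9-fold and 23.8-fold higher, and Alpk3, Tll2, Ankrd7, Tmem132b and Ptpru at least 15.9-fold. Among the largest falls, the growth-arrest protein gene Gas1 (ENSMUSG00000052957, chromosome 13, 60174405 to 60177365) fell 15.6-fold from 64.3 ± 2.98 to 4.12 ± 0.2 CPM, the chemokine Cxcl5 17.7-fold from 5.79 ± 0.419 to 0.326 ± 0.124 CPM and the adrenergic receptor Adra1d 12.2-fold from 16.5 ± 1.33 to 1.36 ± 0.187 CPM.

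Camera called 18 lists, 6 higher and 12 lower. With an estimated correlation 7 were called, those for which no such p is given above. Other divisions of the 6 libraries, each a mix of both groups, called up to 15 lists. Over all camera alternatives the lowest adjusted p of the 18 ran from 2.9e-14 to 0.00338. The value with an estimated correlation was the highest except for antioxidant enzymes (0.202) and heat shock genes (0.122 without genes under 1 CPM in control and H2O2). Changes over 1.5 times smaller with the offsets, in the same direction, were those of Gpx4, Rpl3, Prdx2, Gpx8, Sephs2, Idh2, Ndufv2, mt-Atp6 and Acsl4, and that of Sod2 was larger (−0.26 in place of −0.15).

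A direct count was made of how far pretreatment moved H2O2-changed genes back. Of 8817 genes called in H2O2, 4920 (55.8%) changed in the opposite direction in pretreated H2O2 against H2O2, 2603 that were higher and 2317 that were lower in H2O2; 1973 (22.4%) moved further in the same direction and 1924 (21.8%) were not called again. Of the 4920, 1731 were not called against control, 1429 stayed on the H2O2 side of control and 1760 lay past control. With the offsets 601 of 3321 stayed on the H2O2 side. Where changes of at least 2-fold were required, also against control, 20 of 338 did. That rule itself limits such genes, so the 20 cannot be set against the 1429. Hspa1b, at 12.8, 88.1 and 5.28 CPM in control, H2O2 and pretreated H2O2, went past control, whereas Cdkn1a, at 24.1, 90.7 and 612 CPM, moved further. Independent calls would give 1392 and 1413 opposite genes for those higher and lower in H2O2, and 2805 further ones. Covariance between both changes was −0.1003, and −0.103 to −0.0705 in 20 simulated data sets without an effect of pretreatment. Among genes with at least 1 CPM it was −0.0492, and −0.023 to −0.00919 in the simulations. Simulated sets were filtered on their own counts, which can drop genes seen mainly in pretreated H2O2. Observed and simulated values thus cover unlike genes, and their comparison decides nothing about the reversal. Both comparisons share the H2O2 libraries, and 3 libraries cannot be divided into independent sets with more than 1 each, so part of the excess may come from sharing. With the offsets 3321 of 6811 H2O2 calls were opposite and 1903 moved further. When at least 2-fold changes were required in both, 338 of 1105 were opposite and 241 moved further; genes that moved back by less than 2-fold do not count there.

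**Figure D3:**
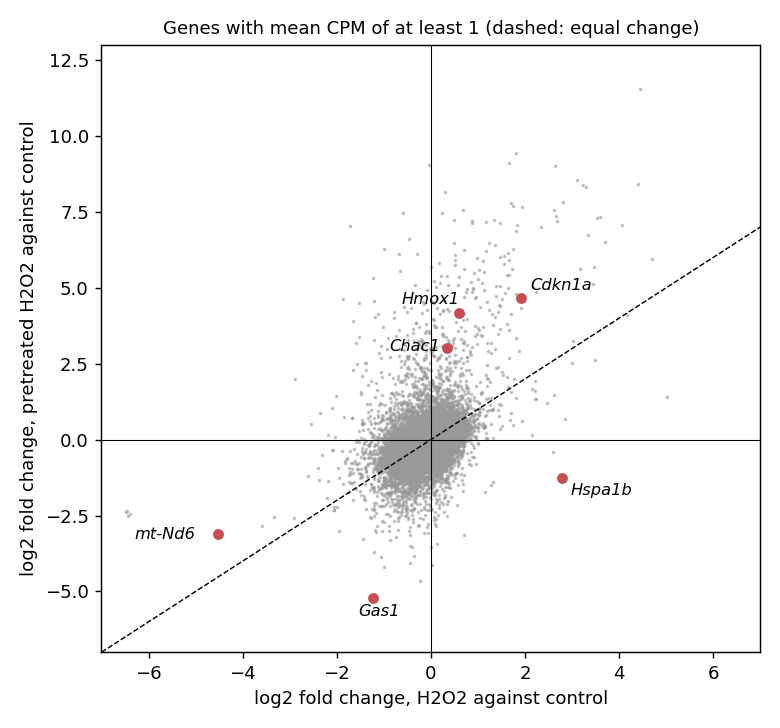
Log2 fold change of H2O2 against control (x axis) and of pretreated H2O2 against control (y axis) for 12852 genes with a mean of at least 1 CPM and a count in every group, with 1 point per gene, 6 named genes in red and a dashed line for equal change. Cdkn1a lies at 1.91 and 4.67, Hspa1b at 2.78 and −1.28, and Gas1 at −1.24 and −5.20.

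Pretreated H2O2 was finally compared with control, to ask how far these cells lay from untreated ones. Hmox1 was 18.0-fold higher, at 1527 ± 20.2 against 85.0 ± 1.83 CPM (log2 fold change 4.17, SE 0.03, adjusted p = 1.4e-16). Cdkn1a was 25.4-fold higher, at 612 ± 6.44 against 24.1 ± 1.63 CPM (SE 0.05, adjusted p = 2.83e-15), and Mdm2 was 13.5-fold higher. Gas1 was 36.8-fold lower, at 4.12 ± 0.2 against 152 ± 0.58 CPM (SE 0.049, adjusted p = 1.04e-15). The mitochondrial share of counts was 0.898 ± 0.017% against 2.66 ± 0.069% in control, and 24106 ± 54.7 genes had a count against 20387 ± 325 (two-sided exact permutation p = 0.1 for both, the smallest possible).

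This comparison called 11424 genes (63.1%), 6088 higher and 5336 lower, 2678 and 1306 of them by at least 2-fold. Control held no count or no more than 12 over the group in 1208 of the 2678. Groups did not overlap in 68.9% of genes, where chance gives 10%. With the replicate block 11181 genes were called, 5900 higher and 5281 lower. Total counts alone gave 5658 higher and 5729 lower, and a filter at 1 CPM gave 4975 and 4891 among 13500 genes. With limma, FPKM gave 3794 higher and 5269 lower among 12873 genes with the minimum level, but 6566 higher and 5572 lower among 30411 without it, and the offsets gave 6784 higher and 4445 lower.

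Integrated stress response genes rose in 33 of 34, also when adjusted over the list alone (median 1.24, adjusted p = 6.78e-14), with Atf4 up 2.27-fold to 658 ± 4.44 CPM and Ddit3 3.26-fold. Targets of p53 rose in 24 of 29 and fell in 2, also when adjusted over the list alone (median 1.06, adjusted p = 1.23e-07), with Plk2 up 6.03-fold to 903 ± 20.4 CPM. Ferroptosis expression markers rose in 11 of 12 and fell in 1, also when adjusted over the list alone (median 1.67, adjusted p = 1.28e-06); Chac1 rose 8.12-fold and Ptgs2 3.11-fold. Targets of NRF2 rose in 23 of 32 and fell in 1, also when adjusted over the list alone (median 0.37, adjusted p = 7.42e-07). Txnrd1 rose 4.12-fold, Slc7a11 2.91-fold, Srxn1 2.40-fold, Nqo1 2.04-fold and Gclm 1.43-fold. Transfer RNA synthetase genes rose in 17 of 20 and fell in 2, also when adjusted over the list alone (adjusted p = 6.43e-05; adjusted p = 0.055 with an estimated correlation), and immediate early genes rose in 24 of 34 and fell in 9, also when adjusted over the list alone (adjusted p = 0.000975; adjusted p = 0.143 with an estimated correlation).

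Antioxidant enzymes rose in 18 of 29 and fell in 4 (19 and 4 when adjusted over the list alone; adjusted p = 0.0265; adjusted p = 0.138 with an estimated correlation). This call was also lost without control replicate 1, without control replicate 2 and with the offsets. Selenoprotein genes rose in 10 of 27 and fell in 10 (11 and 10 when adjusted over the list alone) and did not pass (adjusted p = 0.886). Gpx4, at 174 ± 8.56 against 160 ± 6.05 CPM with overlapping libraries (1.09-fold, adjusted p = 0.0106), was not called with total counts alone, without control replicate 1 or 2, without pretreated replicate 2 or 3, or with limma on FPKM (log2 fold changes of 0.08 to 0.11). Gpx1 was 1.23-fold and Sod1 1.15-fold higher, Cat 1.17-fold and Fth1 1.45-fold. Sod2 was 1.08-fold higher (adjusted p = 0.0279) and lost its call in 10 of the alternatives, among them those without control replicate 1 or 3 or pretreated replicate 1 or 3. Tfrc was 1.55-fold higher and Acsl4 1.27-fold lower. Ribosomal protein genes rose in 77 of 77, also when adjusted over the list alone (median 0.37, adjusted p = 5.35e-14; adjusted p = 0.143 with an estimated correlation). Nuclear respiratory chain subunits rose in 42 of 69 and fell in 3 (43 and 3 when adjusted over the list alone; adjusted p = 0.00226; adjusted p = 0.425 with an estimated correlation, and 0.528 with the offsets).

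Cholesterol synthesis genes fell in 24 of 25, also when adjusted over the list alone (median −1.18, adjusted p = 8.43e-13), with Hmgcs1 down 5.01-fold. Fatty acid synthesis genes fell in 20 of 26 and rose in 3 (20 and 5 when adjusted over the list alone; median −0.59, mean 0.21, adjusted p = 6.88e-06), with Scd2 down 3.28-fold. Fatty acid oxidation genes fell in 16 of 27 and rose in 2, also when adjusted over the list alone (median −0.19, mean 0.12, adjusted p = 0.00367; adjusted p = 0.0613 with an estimated correlation). Interferon response genes fell in 24 of 33 and rose in 6 (25 and 6 when adjusted over the list alone; median −0.86, adjusted p = 1.44e-05), and genes of the G2 and M phases fell in 34 of 36 and rose in 1, also when adjusted over the list alone (adjusted p = 8.43e-13), with Mki67 down 3.41-fold. Fibroblast markers fell in 12 of 13, also when adjusted over the list alone (median −1.15, adjusted p = 7.42e-07), with Pdgfrb down 5.70-fold. Mitochondrially encoded genes fell in 13 of 15 and rose in 2, also when adjusted over the list alone (median −1.68, adjusted p = 2.48e-07; adjusted p = 0.206 with an estimated correlation). The 2 that rose were the ribosomal RNA genes mt-Rnr1, 4.21-fold, and mt-Rnr2, 1.11-fold, both chosen here after their values were seen and without alternatives run for them.

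The largest rise was of Myo15, an unconventional myosin of hair cell stereocilia (ENSMUSG00000042678, chromosome 11, 60469339 to 60528369), without a count in control and at 31.9 ± 1.26 CPM in pretreated H2O2, at least 149-fold higher. Hair cell markers as a list did not pass (4 of 10 higher, 3 lower, adjusted p = 0.604). L1cam, a neural adhesion molecule, at 13.2 ± 1.91 CPM, and the glucose transporter Slc5a2, at 8.05 ± 0.304 CPM, were at least 61.5-fold and 37.6-fold higher, and Cplx1, Mmp25, Cym and Dnah12 at least 22.9-fold. Celsr2, a cadherin of planar cell polarity, stood at 0.0238 ± 0.0413, 0.515 ± 0.175 and 71.4 ± 2.68 CPM in the 3 groups. Read-through from an upstream gene, considered below for newly counted genes as a set, was not examined for these genes singly. The same holds for the largest rises of the other comparisons. Beside Gas1, the adipogenesis-linked Medag fell 14.1-fold from 116 ± 6.09 to 8.27 ± 0.681 CPM, Jade2 12.9-fold and Gprin3 18.3-fold.

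Camera called 16 lists, 9 higher and 7 lower, of which 9 were called with an estimated correlation. Other divisions of the 6 libraries, each a mix of both groups, called up to 14. Over all camera alternatives the lowest adjusted p of the 16 ran from 3.82e-16 to 0.00132, and the value with an estimated correlation was the highest except for respiratory chain subunits. With the offsets the change of Acsl4 was −0.14 in place of −0.34 and that of Sod2 0.33 in place of 0.11.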

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

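Chosen after the data were seen were the alternatives with counts divided by 4, without the mitochondrial chromosome, without genes under 1 CPM in control and H2O2, and with offsets for transcript length and GC content, alone or with the replicate block. Of the 528 values of named genes, 470 kept their direction and their side of the threshold in every alternative, and of the 126 list values 32 did, fry and the estimated correlation included; direction was compared only where at least 1 of the 2 values was called. Single alternatives gave 12304 gene values on the same side, 118 that lost a call, 17 that gained one and 30 in the opposite direction; for lists these were 1875, 53, 63 and 7.

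Requiring an absolute log2 fold change of at least 1 left 1105 of 8817 genes in H2O2 against control, 3648 of 11511 in pretreated H2O2 against H2O2, 3984 of 11424 in pretreated H2O2 against control, and 338 of 4920 opposite genes; fewer genes follow from the rule itself. Leaving out any 1 library gave 8129 to 8725, 10908 to 11911 and 10761 to 11813 called genes in that order, and 4518 to 4799 opposite genes. DESeq2 called 8760, 11703 and 11737 genes. Correlations of residuals between libraries of 1 replicate number were 0.332, 0.137 and 0.249 for control with pretreated H2O2. They were −0.101, −0.073 and 0.215 for control with H2O2 and 0.004, 0.043 and 0.179 for H2O2 with pretreated H2O2. Numbers may thus pair the libraries in the first, and the last 2 gave less sign of pairing. With the replicate block and the offsets together 3190 genes were opposite.

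Camera with an estimated correlation called 0, 7 and 9 lists in the 3 comparisons, against 20, 18 and 16 with the preset correlation, and fry called 32, 40 and 38. Fry takes no account of the other genes, which camera does. It gave the opposite direction to camera in pretreated H2O2 against H2O2 for selenoproteins (adjusted p = 0.000487), glutathione genes (0.000209), iron handling (1.95e-06), hypoxia targets (1.1e-06) and mitochondrially encoded genes (0.0132), and in pretreated H2O2 against control for iron handling (5.42e-08) and extracellular matrix genes (3.06e-05). The cause was not tested.

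With the offsets, alone or with the replicate block, some named genes changed direction; values are log2 fold changes, equal in both unless 2 are given. In H2O2 against control these were B2m (−0.07), Gclm (0.15), Acaca (0.02), Fasn (0.16), Tfrc (0.20), Chaf1a (0.19), Mtf1 (0.23), Ntrk3 (0.35), Myo6 (0.04), Gsto1 (−0.07), Slc7a11 (0.44 and 0.43), Sparc (0) and Srxn1 (−0.07), the last called in neither. In pretreated H2O2 against H2O2 they were Gpx1 (0.01) and Cat (0.13), and in pretreated H2O2 against control Myo6 (0.01). The cause was not tested. Depth limits genes of few counts: with 12 counts as the floor, 232, 417 and 675 called genes had a group without any count, and for these only a lower bound of the fold can be given.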

Other observations

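Chosen after the result was seen were the counts of mitochondrial genes by strand with the values of mt-Nd6 and mt-Te in pretreated H2O2, the tests with offsets and of the share of counts freed by mitochondrial RNA, the tests for exchanged libraries, the comparison of receptor genes with genes of matched length, and the comparison of upstream with downstream neighbours.

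Mitochondrial genes were counted by strand, without a test of a difference between strands. In H2O2 against control 23 of 25 tested genes of the plus strand fell and 1 rose, and 9 of 9 of the minus strand fell, among them mt-Nd6 from 294 ± 11.9 to 12.7 ± 1.74 CPM and the glutamate transfer RNA mt-Te from 11.3 ± 0.549 to 0.188 ± 0.0327 CPM. In pretreated H2O2 against H2O2, minus-strand genes rose in 8 of 9 with none lower, with mt-Nd6 at 33.9 ± 2.96 and mt-Te at 1.40 ± 0.213 CPM, while plus-strand genes rose in 14 of 25 and fell in 9. In pretreated H2O2 against control, 21 of 25 plus-strand genes fell and 2 rose, and 9 of 9 minus-strand genes fell. Whether the authors counted reads by strand is not given in the sources used here, and transfer RNA genes are shorter than the reads. No explanation was tested.

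Cell-type markers did not pass as lists by camera in pretreated H2O2 against H2O2 apart from those of fibroblasts, which had adjusted p = 0.000196 and adjusted p = 0.099 with an estimated correlation. Cochlear supporting cell markers fell in 9 of 18 and rose in 5 (adjusted p = 0.189; over the camera alternatives from 0.034 without genes under 1 CPM in control and H2O2, where the list was called lower, to 0.25 with an estimated correlation), with Id3, a repressor of differentiation, down from 230 ± 8.05 to 73.2 ± 3.51 CPM and the cell cycle inhibitor Cdkn1b down 2.22-fold. Hair cell markers rose in 5 of 10 and fell in 2 (adjusted p = 0.285), and besides Myo15 the glutamate transporter Slc17a8 stood at 0.0276 ± 0.0479 and 1.36 ± 0.712 CPM. Hypoxia targets rose in 8 of 26 and fell in 14 (adjusted p = 0.546), although the growth factor Vegfa rose 6.47-fold from 71.3 ± 2.58 to 462 ± 3.22 CPM and Ndrg1 4.43-fold. Endoplasmic reticulum chaperones rose in 10 of 25 and fell in 7 (adjusted p = 0.371), with Hspa5 up 2.13-fold to 2368 ± 50 CPM. The cytokine Lif rose 32.1-fold from 14.8 ± 0.496 to 473 ± 2.7 CPM among inflammatory genes of which 15 of 27 rose and 9 fell (adjusted p = 0.392).

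Ribosomal protein and nuclear respiratory chain genes were higher in H2O2 than in control. With offsets for transcript length and GC content the median log2 fold change of the first list went from 0.664 to 0.304 (95% interval 0.284 to 0.34). That of the second went from 0.5 to 0.169 (0.128 to 0.19). This argues against the bias that the offsets capture as the whole cause, although over 50% of each median moved with them. The offsets used the longest annotated transcript of each gene, so bias that they miss could not be tested. The share of counts freed by the fall of mitochondrial RNA allows all other genes a log2 rise of at most 0.025, before any scaling, which argues against it as the cause for both lists. Length or GC bias, in part or beyond the offsets, and an effect of H2O2 both stay open.

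More genes had a count in pretreated H2O2 than in the other 6 libraries. Thinning all libraries to 1 total kept 94.5% of the excess, which argues against deeper sequencing. Of 1353 olfactory and vomeronasal receptor genes without a count in the other 6 libraries, 1.183% (95% interval 0.677 to 1.913) had a count in all 3 pretreated libraries. Other such coding genes matched for length gave 9.4% (8.29 to 10.55). For genes with a count in all 3, this argues against DNA spread over the whole genome. They were 780 of the 4058 such genes with a count in any pretreated library. For the others such background was not tested and stays open. Genes new in the pretreated group more often had an expressed neighbour on the same strand only upstream (102) than only downstream (64; odds ratio against genes without any count 2.78, 1.99 to 3.89), so read-through may add to the excess, but 132 of 780 had any expressed upstream neighbour within 20 kb, on both sides or only upstream, and genes without any count lack read-through by definition. A change of transcription with pretreatment stays open and was not tested separately.

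Stress response, p53 and ferroptosis marker lists, which share members, lay further from control in pretreated H2O2 than in H2O2. All 9 of 9 libraries correlated best with a library of their own group, which argues against a single library exchanged between groups, and the lowest median of the 3 lists with the offsets was 1.113, which argues against length or GC bias. Labels of the whole H2O2 and pretreated groups exchanged cannot be told apart from the pattern, since no transcript level is fixed by the labels (Hmox1 log2 fold change 3.57). No group received the nanoreactor alone, so its own effect without H2O2 stays open and may account for part of the 3.57.

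The 6 libraries of each comparison can be divided into 3 and 3 in 10 ways, so the share of divisions with a result as large is never under 0.1. Every division but the real one mixes libraries of both groups on each side. Part of the group difference therefore stays in it, and its numbers do not show what no difference would give. In each case 1 of 10 divisions, the real one, gave a result as large. Real numbers of called genes were 8817, 11511 and 11424, where the highest other division gave 0, 0 and 1 by edgeR. Called lists were 20, 18 and 16, with 6, 15 and 14 as the highest others. Opposite genes were 4920, with 0 as the highest other. That 0 follows from the absence of any called gene in those divisions, so it says nothing about the reversal. Where replicate numbers may pair libraries, in pretreated H2O2 against control, the highest other of the 4 divisions that part all 3 pairs called 1 gene.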
